A study of Macaca fascicularis with 4 samples.

How the data were processed

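The data were gene counts from 4 full-length RNA libraries of Macaca fascicularis: liver, muscle, oWAT and sWAT, with 1 library per tissue. Per the labels' protocols, RNA of the same tissue from 5 monkeys was pooled into each library, and the libraries were sequenced on the PacBio Sequel II platform, which reads whole cDNA molecules. The aligner was minimap2 2.24, per the submitters' processing notes. Read filtering, the assignment of reads to genes, the genome build and the gene annotation are not given in the sources used here. Strand use and the handling of reads shared by near-identical genes are also not given, so values of gene families such as the myosin heavy chains, the cytochrome P450s and the UGT2B genes carry that uncertainty.

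The deposited files hold whole-number counts per gene that were not normalized, and list only genes with at least 1 count; a gene not listed in a library was taken as 0. Tissue groups were taken from the labels. The names of the oWAT and sWAT files carry other abbreviations for the tissues, and the labels were followed. Each file also has an entry for counts that name no gene, which was left out of the library totals. That entry held 103719 counts in liver, 73484 in muscle, 96374 in oWAT and 76555 in sWAT, or 19.2%, 14.3%, 19.5% and 16.6% of the file.

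The files name 13982 genes in all, of which 8901 had counts in all 4 libraries and 1214 carried an Ensembl identifier in place of a symbol. Symbols were used as the files give them; 12266 matched a symbol of the RefSeq table for the assembly T2T-MFA8v1.1, and 0 of the identifiers matched it. As the build behind the counts is not given, no coordinates are reported. Genes known by identifier alone made up 7.12% of counts in liver, 5.48% in muscle, 5.69% in oWAT and 4.43% in sWAT, and were counted but not named. Values of some other genes are not reported here.

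Counts were scaled to the library total (CPM). For each gene and pair of libraries, the fold was the ratio of scaled counts, with an exact 95% Clopper-Pearson interval from the binomial share of the 2 counts. A gene was called higher where it had at least 10 counts in the higher library and the lower bound of the interval was above 2. For liver and for muscle the bound had to hold against each of the other 3 libraries, and for WAT in all 4 pairings of oWAT or sWAT with liver or muscle; oWAT and sWAT were then compared with each other. The fold printed is that of the pairing with the smallest fold. Against 0 counts, the fold was computed with a floor of 3 counts in that library and is given as "at least". It does not cover a library with 1 to 3 counts of that gene. It is also not an interval bound: for ALB over sWAT it is 17989, while the exact lower bound of that pairing is 14629. The floor equals 6.86 CPM in liver, 6.82 in muscle, 7.56 in oWAT and 7.81 in sWAT. The intervals cover counting error only: the reads carry no molecular identifiers here, and 1 library per tissue allows no estimate of the spread between animals. No p-values were computed.

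Gene lists, 38 in number, covered pathways and markers of the cell types the tissues could hold. A list member was measured where it had at least 10 counts over the libraries compared. For lists with at least 3 measured members, the median log2 ratio after adding 0.5 counts was given with an order-statistic interval, and placed as a percentile among 10000 random lists of the same size matched on mean expression in 10 bins. In comparisons with several libraries the ratio is to the highest of the other libraries, so that random lists have medians below 0. The lists, the calling rule and the rule for naming genes were fixed before the data were examined. That rule named, for liver, muscle and the pair of WAT libraries, the 10 most abundant genes of a library and the 15 called genes with the largest lower bound. Between oWAT and sWAT it named the 12 called genes with the largest lower bound in each direction, and up to 4 examples were taken per list. Exceptions named after their values were seen are APOE, C7 against liver, LDHB, ARG1, AQP7, MYH4, ADIPOQ in muscle, FBLN1, COL4A2, NID1 and LOX between oWAT and sWAT, and the members of a list that gained or lost a call.

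Alternatives were scaling by edgeR 4.0.16 TMM factors and by DESeq2 1.42.0 size factors (R 4.3.3), totals without the 10 most abundant genes of any library, other minimum counts, a wider interval of higher confidence, bounds of 1 and 4, thinning to the smallest library, other pseudocounts, and other forms of the correlation. DESeq2 and edgeR were used for scaling factors alone. TMM factors were 0.671 for liver, 0.911 for muscle, 1.35 for oWAT and 1.21 for sWAT, and the DESeq2 size factors were 0.722, 0.985, 1.30 and 1.11. Other computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

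The calling rule was tested on Poisson counts of 13982 genes, simulated at the real totals from 1 profile pooled over the libraries. Of the genes, 200 were changed by known folds, and the rule was then applied. For oWAT over sWAT it called 0 of the unchanged genes, 42 of 50 genes changed 4-fold and 50 of 50 changed 8-fold. For liver over the other 3 libraries it called 0 unchanged genes, 38 of 50 at 4-fold and 50 of 50 at 8-fold. The other changed genes, at 1.5-fold and 2-fold, did not exceed the rule's bound of 2. The simulation holds counting error alone, so it gives no error rate for differences between animals, in preparation or in composition.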

Results

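Full-length RNA sequencing was performed on 4 tissues of the cynomolgus monkey (Macaca fascicularis): liver, muscle, and the tissues labelled oWAT and sWAT. The labels do not spell out oWAT and sWAT; WAT is the usual abbreviation for white adipose tissue. Each tissue is represented by 1 library, made from RNA of 5 monkeys pooled before library preparation. There are therefore no replicates. Intervals of folds, shares and counts cover counting error alone. Intervals of list medians cover the spread between the members of a list. Neither kind covers the spread between animals. The series was made to describe transcripts across tissues, and the gene counts permit a comparison of tissues but not of isoforms. Transcript length was not used, so abundance ranks and list counts describe the libraries as sequenced.

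The counts assigned to genes totalled 437587 in liver, 439872 in muscle, 396797 in oWAT and 383896 in sWAT. Genes with at least 1 count numbered 10902, 11316, 12023 and 11636 in the same order, and genes with at least 10 counts numbered 4944, 5809, 6563 and 5997. The 10 most abundant genes took 24.0% of the liver counts (exact 95% binomial interval 23.9 to 24.1) and 17.9% of the muscle counts (17.8 to 18.0). They took 7.54% in oWAT (7.46 to 7.62) and 14.3% in sWAT (14.2 to 14.4). Across 10127 genes with at least 10 counts over the 4 libraries, oWAT and sWAT were the most alike, with a Spearman correlation of 0.89. Muscle correlated with oWAT and with sWAT at 0.69, liver with oWAT at 0.49, liver with sWAT at 0.48, and liver with muscle at 0.39. These are correlations across genes, which are not independent replicates, so no p-value is attached.

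The liver library was led by transcripts of secreted plasma proteins. ALB, which encodes serum albumin, had 61515 counts (140578 CPM) against 0 in muscle and sWAT and 1 in oWAT, at least 17989-fold higher than in sWAT. The fibrinogen chains FGA, FGG and FGB were at least 1260-fold, 1094-fold and 699.5-fold higher than in sWAT, where each had 0 counts, and the clotting-system genes PLG (plasminogen, over oWAT) and HRG were at least 1359-fold and 521-fold higher. Metabolic enzymes stood at similar heights: BHMT and MAT1A, both of methionine metabolism, at least 1326-fold and 1003-fold higher than in sWAT, CYP2E1, a cytochrome P450, at least 1116-fold, and CPS1, which catalyses the entry step of the urea cycle, at least 549-fold. APOB, the structural protein of very-low-density lipoprotein, was at least 858-fold higher than in sWAT. GC (vitamin D binding protein), UGT2B20, AOC1 and ITIH1 followed, at least 627-fold, 557-fold, 529-fold and 443-fold higher than in sWAT. These folds are ratios to the floor that stands in for 0 counts, and the exact lower bounds are smaller. The bounds over sWAT were 697 for APOB, 510 for GC, 452 for UGT2B20, 430 for AOC1 and 360 for ITIH1.

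In all, 533 of the 4944 genes with at least 10 liver counts were higher in liver than in each of the other 3 libraries, with the lower bound of the exact 95% interval of the fold above 2 each time. Of these, 198 had 0 counts in the other 3 libraries and 38 carried an identifier without a symbol. Not all abundant liver genes were liver-restricted. TF (transferrin) was 30.2-fold higher than in sWAT (95% interval 26.9 to 33.9), and the complement gene C3 was 4.32-fold higher than in oWAT (4.04 to 4.62). FN1 (fibronectin) was 1.42 times its sWAT level (1.34 to 1.495) and was not called; it passed with scaling by trimmed mean of M-values (TMM, 2.57-fold) and by DESeq2's size factors (2.48-fold).

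By gene list, all 20 measured plasma protein genes were higher in liver, with ALB, TF, ITIH4 (159-fold, 97.8 to 279) and GC the most abundant. The same held for 20 of 21 coagulation and fibrinolysis genes, 20 of 21 genes of the urea cycle and amino acid breakdown, 17 of 18 genes of xenobiotic metabolism and 14 of 14 hepatocyte markers. Median log2 ratios to the highest of the other 3 libraries were 7.81 for plasma proteins, 8.73 for coagulation, 6.73 for the urea cycle list and 7.03 for xenobiotic metabolism. With zeros set to the floor of 3 counts they were 6.33, 7.43, 5.31 and 4.94. Each of these 4 lists lay at the 100th percentile of 10000 random lists matched on expression. CYP3A4 was at least 795-fold higher than in sWAT, CYP2C8 at least 600-fold higher than in oWAT, and ARG1 (arginase) at least 138-fold higher than in sWAT. Among 9 measured apolipoproteins 8 were higher, including APOA5 (at least 118-fold) and APOA1 (at least 68.4-fold over sWAT), while APOE was 1.86 times its sWAT level (1.57 to 2.21) and was called only with TMM and DESeq2 scaling, which gave 9 of 9.

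Complement was split, with 12 of 17 measured genes higher in liver, among them C9 (at least 409-fold over sWAT), C8B (at least 206-fold) and C5 (36.4-fold over sWAT, 22.3 to 64.1). C7 was not among them and was 0.153 times its oWAT level (0.129 to 0.181). Of 13 genes of bile acid synthesis and transport 9 were higher, including the uptake transporter SLCO1B1 (66.7-fold over oWAT, 41.5 to 115) and AKR1D1 (at least 74.3-fold). Of 17 genes of gluconeogenesis and glycogen 8 were higher, with PCK1, the cytosolic enzyme that commits carbon to glucose synthesis, 15.6-fold over oWAT (12.4 to 19.9). Fatty acid oxidation had 7 of 24 members higher, among them ACAA2 (5.82-fold over oWAT, 4.47 to 7.70). Cholesterol synthesis had 5 of 20, with INSIG1 at 4.47-fold (3.47 to 5.83). With TMM or DESeq2 scaling the oxidation count became 12 and the cholesterol count 10 and 9. In the endothelium list PROX1 (31.8-fold, 13.3 to 99.2) and STAB2, a receptor of liver sinusoids (12.2-fold, 4.51 to 46.5), were the 2 of 14 higher in liver. The other 12 lay below the highest of the other libraries, and the list had a median log2 ratio of -3.23 at the 0.14th percentile of random lists.

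**Figure D1:**
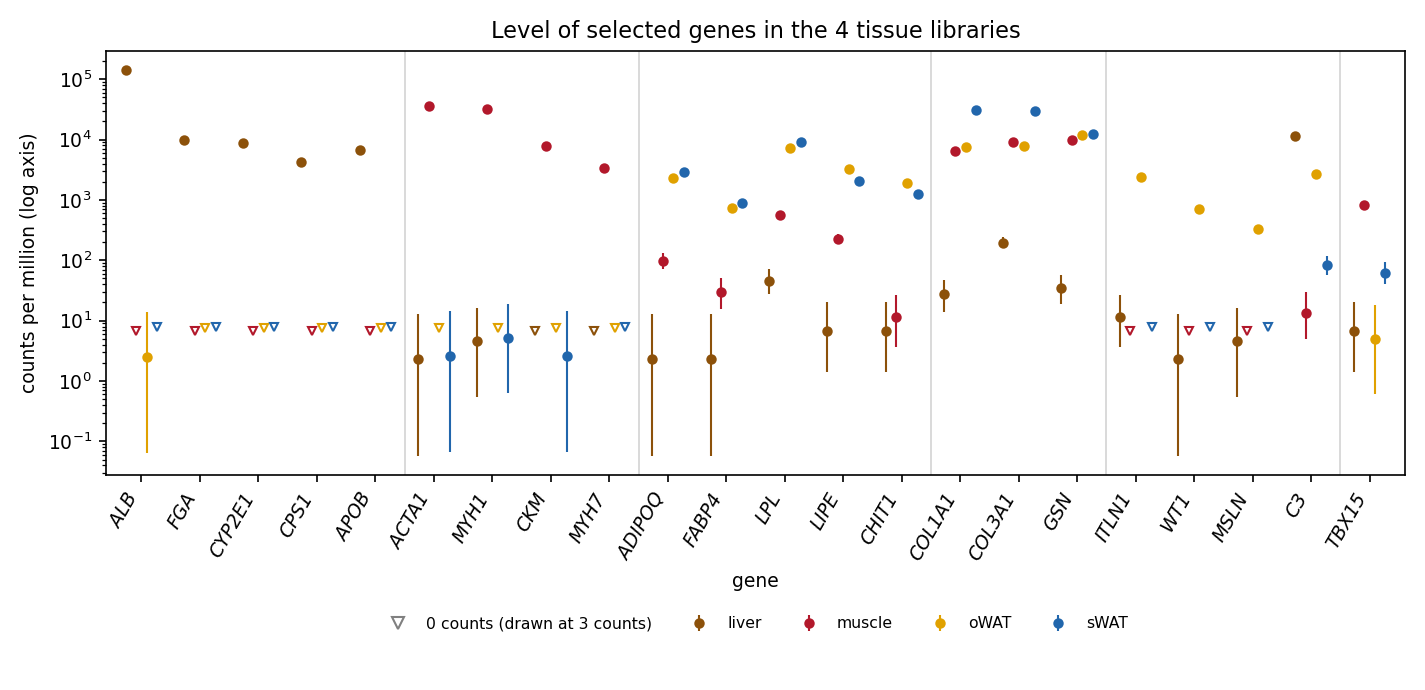
Level of selected genes in the 4 libraries, in CPM on a log axis; circles are libraries coloured by tissue, vertical lines are exact 95% Poisson intervals, and open triangles mark 0 counts and are drawn at the level of 3 counts. ALB reaches 140578 CPM in liver and ACTA1 35981 in muscle, while ADIPOQ, FABP4 and LPL are highest in the oWAT and sWAT libraries.

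The muscle library was led by sarcomere genes. ACTA1 (skeletal alpha-actin) had 15827 counts against 0 in oWAT and 1 each in liver and sWAT, at least 4759-fold higher than in oWAT. MYH1, a fast myosin heavy chain with 2 counts each in liver and sWAT, was at least 4269-fold higher than in oWAT, and MYBPC1, a myosin-binding protein with 1 count in liver, at least 4056-fold higher than in sWAT. The giant thin-filament protein NEB was at least 1001-fold higher than in sWAT and MYBPC2 at least 907-fold, and TTN (titin), which had 54 counts in liver, was 93.1-fold higher (71.2 to 124). ATP2A1, the calcium pump of fast fibres, was 275-fold higher than in oWAT (197 to 398). Genes of energy supply stood beside them: CA3 (carbonic anhydrase 3) at least 1057-fold over sWAT, CKM (muscle creatine kinase) at least 1044-fold over oWAT, ENO3 at least 463-fold over sWAT, and PYGM, the muscle glycogen phosphorylase, 393-fold (180 to 1071).

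Of 5809 genes with at least 10 muscle counts, 390 were higher than in each of the other 3 libraries, 105 of them with 0 counts in the others and 11 without a symbol. ACTN2 (at least 584-fold over sWAT), MYH7, the slow myosin heavy chain (at least 427-fold), NRAP (at least 326-fold over sWAT), CASQ1 (at least 218-fold) and DES, the intermediate filament desmin (201-fold, 122 to 359), completed the leading genes. Connective-tissue transcripts were abundant in muscle too but not higher there. GSN (gelsolin) was 0.817 times its sWAT level (0.784 to 0.851), a ratio that became 1.09 with TMM and 1.05 with DESeq2 scaling, and COL3A1 was 0.306 times its sWAT level (0.295 to 0.317).

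Nearly the whole contractile programme was higher in muscle: 31 of 34 measured thick and thin filament genes, 11 of 12 fast fibre genes, 9 of 12 slow fibre genes and 11 of 11 myofibre markers. Median log2 ratios were 6.60 for the filament list, 8.37 for fast fibre and 4.26 for slow fibre genes (5.23, 6.26 and 3.11 with zeros at the floor), each at the 100th percentile of random lists. Fast fibre members included ACTN3 (47.8-fold, 36.6 to 63.6); slow fibre members included TNNI1 (at least 39.0-fold) and ATP2A2 (7.02-fold, 4.58 to 11.2). Calcium handling had 14 of 15 genes higher, such as SYPL2 (264-fold, 90.0 to 1280) and SRL (105-fold, 48.1 to 288). Energy buffering and glycolysis had 15 of 16, such as PFKM (134-fold, 83.7 to 231). LDHB, the exception, was 0.344 times its oWAT level (0.1804 to 0.624). Myosin heavy chains are close copies of each other, and the authors' treatment of shared reads is not given in the sources used here. The split among MYH1, MYH4 and MYH7 is therefore uncertain, and MYH2 was not among the names analysed here.

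Other lists contributed few muscle genes. The glycogen list had 4 of 17 higher (PYGM, GYS1, PPP1R3A and FBP2), with GYS1, glycogen synthase, at 4.08-fold (3.22 to 5.22). Fatty acid oxidation had 2 of 24, UCP3 (at least 64.0-fold) and CPT1B (at least 9.60-fold over sWAT), the muscle form of the carnitine shuttle enzyme. Of 12 immediate early and heat shock genes, BAG3 (12.4-fold, 7.60 to 21.7) and NR4A1 (10.005-fold, 5.40 to 20.6) were higher. Among 12 developmental regulators of fat depots, TBX15 (13.1-fold over sWAT, 8.63 to 20.6) and HOXC10 (at least 4.07-fold) were higher in muscle. Nuclear oxidative phosphorylation had 0 of 12 called, and its median log2 ratio of 0.41 turned to -0.032 with TMM and -0.030 with DESeq2 scaling. That list has 36 members, of which 19 had counts and 12 were measured, so its values do not cover the rest. Adipocyte genes had 0 of 21 higher in muscle but were present there: ADIPOQ had 43 counts (97.8 CPM).

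The oWAT and sWAT libraries shared a set of genes that stood above liver and muscle, with adipocyte genes among them. ADIPOQ, which encodes adiponectin, was 23.6-fold higher in the lower of the WAT libraries than in muscle (17.4 to 32.8), FABP4, a fatty acid carrier of adipocytes, 24.9-fold (14.3 to 47.3), LPL (lipoprotein lipase) 12.5-fold (10.98 to 14.3), LIPE (hormone-sensitive lipase) 8.97-fold (7.28 to 11.2) and the fatty acid transporter CD36 8.28-fold (7.21 to 9.55). CIDEC, a lipid droplet protein, had 33 counts in oWAT and 38 in sWAT against 0 in liver and muscle, at least 12.1-fold. CHIT1 (chitotriosidase), which had the largest lower bound of the set, was 111-fold higher (47.2 to 343) and ITGAX, the integrin CD11c, 37.6-fold (14.3 to 140). Neither of them is in the adipocyte list or in the macrophage list, so the macrophage result below does not cover them. The others leading the set were OXTR, the oxytocin receptor (25.5-fold), ALDOC (21.1-fold), GABRE (19.4-fold), MMP19 (18.9-fold), APOL6 (14.5-fold), MMD (13.5-fold) and LAMA4 (8.43-fold).

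The rule called 233 of 5520 genes, of which 9 had 0 counts in both liver and muscle and 7 had no symbol. The count was 68 with TMM and 71 with DESeq2 scaling, all of them within the 233, and it was 1154 against liver alone, a comparison added after the data were seen. The most abundant WAT transcripts were mostly not specific to WAT: relative to muscle, GSN was 1.21-fold (1.16 to 1.26), ACTB 1.33-fold (1.25 to 1.41), COL1A1 1.17-fold (1.11 to 1.23), COL1A2 1.30-fold (1.22 to 1.39), SPARC 1.77-fold (1.66 to 1.90) and PSAP 2.10-fold (1.95 to 2.27), and none of these was called. COL3A1 was 0.854 times its muscle level (0.815 to 0.896) and FN1 0.380 times its liver level (0.356 to 0.405). With TMM scaling GSN, COL1A1, COL1A2 and ACTB lay below muscle, at 0.819, 0.789, 0.883 and 0.9986, and with DESeq2 scaling the first 3 of them did. SCD, the desaturase that makes oleate, was called at 3.38-fold (3.17 to 3.60), and the lysosomal protease CTSB at 2.57-fold over liver (2.34 to 2.84), a call lost with TMM (1.42) and DESeq2 scaling (1.47).

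Of 21 measured genes of adipocyte identity, 15 were higher in both WAT libraries, with a median log2 ratio of 2.84 (2.67 with zeros at the floor) at the 100th percentile of random lists. They included PLIN4 (5.67-fold, 4.67 to 6.93) and PLIN1 (7.27-fold, 4.79 to 11.5), which coat lipid droplets. The count was 12 with TMM or DESeq2 scaling, with CFD, PPARG and SLC7A10 lost. Lipolysis and lipid droplet genes had 8 of 15 higher, including PNPLA2, the adipose triglyceride lipase (4.43-fold, 2.48 to 8.42), and AQP7 (11.6-fold, 4.67 to 37.3); PNPLA2 and PLIN3 lost the call with the other scalings. Fatty acid and triglyceride synthesis had 5 of 20, including ELOVL5 (6.70-fold, 5.54 to 8.14) and FASN (2.72-fold, 2.32 to 3.19). Its median log2 ratio of 0.35 became -0.47 with TMM and -0.45 with DESeq2 scaling, under which only SCD and ELOVL5 were called. The thermogenic list has 14 members, of which 8 had counts and 5 were measured. CIDEA (at least 6.08-fold) was the only one called, and it is also counted in the adipocyte and lipid droplet lists above.

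Among stromal lists, 5 of 29 extracellular matrix genes were higher in both WAT libraries, including TIMP3 (3.75-fold, 3.05 to 4.65) and the basement membrane genes COL4A2 (3.13-fold, 2.48 to 3.97) and LAMB1 (5.65-fold, 3.80 to 8.67); 3 remained with the other scalings, without COL4A2 and LUM. Fibroblast markers had 3 of 17 higher (LUM, PDGFRA and CFD) and 0 with TMM or DESeq2 scaling. Among 15 macrophage markers CD68 was higher (7.93-fold, 4.41 to 15.5), and the list's median log2 ratio of 0.67 turned to -0.33 and -0.32 with TMM and DESeq2 scaling. Endothelium (14 genes measured), smooth muscle and pericyte (13) and mesothelium (11) had 0 called in this comparison.

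The oWAT library differed from sWAT above all in mesothelial genes. ITLN1, which encodes the secreted lectin omentin, had 964 counts in oWAT (2429 CPM) and 0 in sWAT, at least 311-fold higher. WT1, a transcription factor of the mesothelium, had 277 against 0 (at least 89.3-fold), MSLN (mesothelin) 130 against 0 (at least 41.9-fold), LRRN4 84 against 0 (at least 27.1-fold), UPK1B at least 18.1-fold and KRT19 at least 15.5-fold. ALOX15, a lipoxygenase, had 312 counts against 3, a ratio of 101 (34.1 to 491), and WIF1, a secreted inhibitor of Wnt signalling, 127 against 1, a ratio of 123 (21.7 to 4891). C3 was 31.7-fold higher (22.3 to 46.7), CLIC5 27.8-fold (14.4 to 61.6), ALDH1A2, an enzyme of retinoic acid synthesis, 26.8-fold (12.8 to 67.6), and the desmosome gene DSP at least 27.4-fold.

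The sWAT library was higher in fibrillar collagens. COL1A1 reached 31396 CPM in sWAT against 7571 in oWAT, 4.15-fold higher (3.98 to 4.32), COL3A1 3.82-fold (3.67 to 3.98) and COL1A2 3.44-fold (3.27 to 3.61). COL5A2 was 3.64-fold higher (2.95 to 4.53), COL16A1 5.07-fold (3.15 to 8.54) and the laminin chain LAMA2 5.68-fold (3.42 to 9.99). Among less abundant genes, ANGPTL5 (32 counts against 0) was at least 11.03-fold and STMN2 (24 against 0) at least 8.27-fold higher. MFAP5, a microfibril protein, had 26 counts against 1 (26.9-fold, 4.41 to 1102), EPHA3 21 against 1 (21.7-fold, 3.49 to 898), GFRA1 49 against 7 (7.24-fold, 3.26 to 18.9) and TBX15, a T-box regulator, 24 against 2 (12.4-fold, 3.08 to 108).

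In total 94 of 6563 genes were higher in oWAT and 46 of 5997 were higher in sWAT, so that 67.1% of the calls were higher in oWAT. That share was 53.3% with TMM scaling (80 and 70 genes), 47.4% with DESeq2 size factors (74 and 82), 56.5% without the 10 most abundant genes of any library in the totals (83 and 64) and 56.1% without the extracellular matrix list in the totals (83 and 65), the last chosen after the data were seen. Of the 94 genes, 29 had 0 counts in sWAT and 11 had no symbol; of the 46, 4 had 0 counts in oWAT and 1 had no symbol. Each depot has 1 library, so the test compares these libraries and not the depots.

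**Figure D2:**
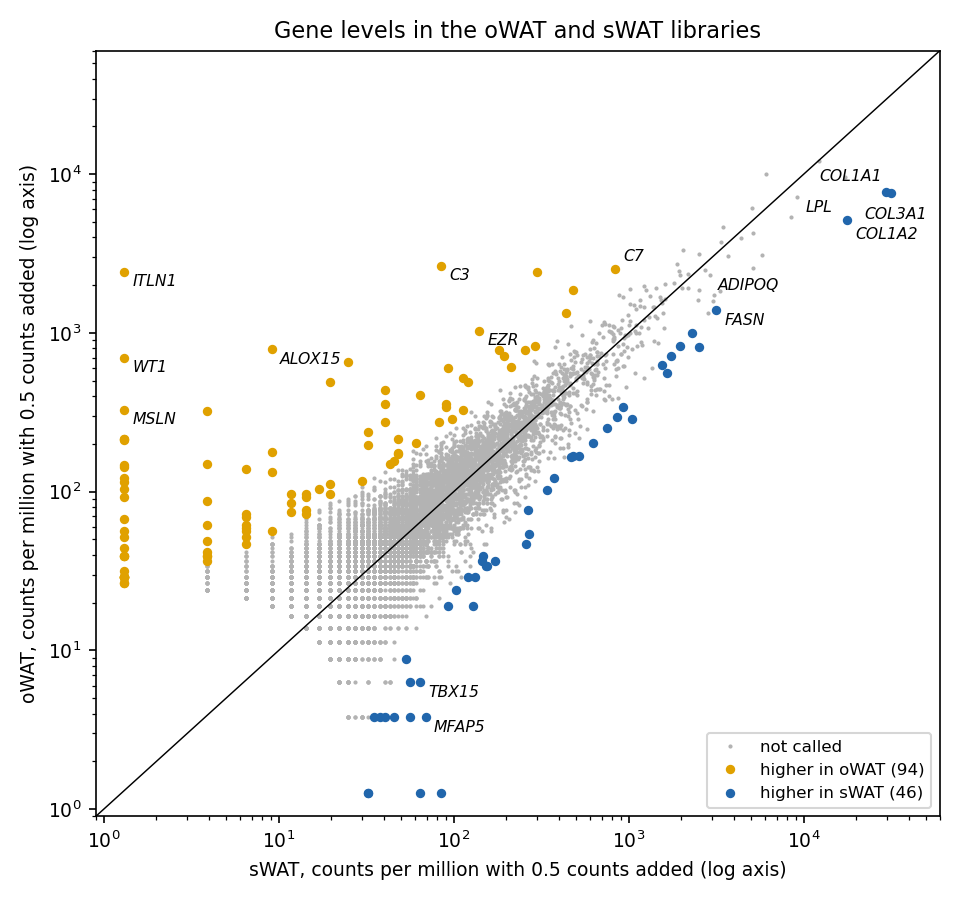
Each point is a gene, with its level in the sWAT library on the horizontal axis and in the oWAT library on the vertical axis, both in CPM after adding 0.5 counts, on log axes; the line marks equal levels. Yellow points are the 94 genes called higher in oWAT, with ITLN1, WT1 and MSLN at 0 counts in sWAT, and blue points the 46 called higher in sWAT, with COL1A1, COL3A1 and COL1A2 the most abundant.

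By list, 9 of 10 measured mesothelium markers were higher in oWAT, with a median log2 ratio of 6.66 (4.06 with zeros at the floor) at the 100th percentile of random lists. CLDN1 (4.05-fold, 2.06 to 8.66) lost its call with TMM and DESeq2 scaling, leaving 8. Among 10 depot regulators WT1, GATA5 and BNC1 (the last 2 at least 3.55-fold) were higher in oWAT and TBX15 was higher in sWAT; WT1 and BNC1 belong to the mesothelium list as well. C3 and C7 (3.02-fold, 2.66 to 3.44) were the complement genes higher in oWAT, of 8 measured. JCHAIN, the joining chain of secreted antibodies, was 16.8-fold higher (5.43 to 84.0), SPP1 (osteopontin) 3.69-fold (2.84 to 4.83) and ALDH1A1 3.06-fold (2.43 to 3.88).

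Extracellular matrix genes leaned towards sWAT, with 9 of 29 higher there, a median log2 ratio of oWAT over sWAT of -0.86 (-1.23 to -0.41) and a position at the 0th percentile of random lists. Beside the collagens these were TIMP3 (2.30-fold, 2.04 to 2.60), COL4A2 (2.42-fold, 2.10 to 2.78), NID1 (2.92-fold, 2.36 to 3.64), LOX, which cross-links collagen (2.87-fold, 2.15 to 3.86), and LAMA2, whereas FBLN1 was 3.09-fold higher in oWAT (2.59 to 3.70). The list took 11.7% of all sWAT counts and 4.58% of oWAT counts. Fibroblast markers pointed both ways, with COL1A1, COL3A1 and MFAP5 higher in sWAT and C7 higher in oWAT, of 17 measured, and a median log2 ratio of -0.42 (-1.32 to 0.09) at the 0.09th percentile. In the endothelium list VWF was higher in sWAT (2.44-fold, 2.10 to 2.84), and the median over 11 genes was -0.65 (-1.29 to -0.27), at the 0.06th percentile.

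Adipocyte identity genes had 0 of 20 called in either direction, with a median log2 ratio of -0.26 (-0.36 to 0.33) at the 0.42nd percentile, and of -0.41 and -0.44 with TMM and DESeq2 scaling. For fatty acid and triglyceride synthesis 2 of 20 were higher in sWAT, FASN (2.28-fold, 2.06 to 2.53) and ELOVL6 (10.9-fold, 2.65 to 95.5). Fatty acid oxidation had 0 of 20 called, with a median of 0.51 (0.21 to 0.95) at the 99.3rd percentile of random lists, and lipolysis (13 genes measured), nuclear oxidative phosphorylation (11), macrophage (14) and smooth muscle and pericyte (11) lists had 0 called. With DESeq2 scaling MYH11 and PDGFRB of the last list were called higher in sWAT.

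**Figure D3:**
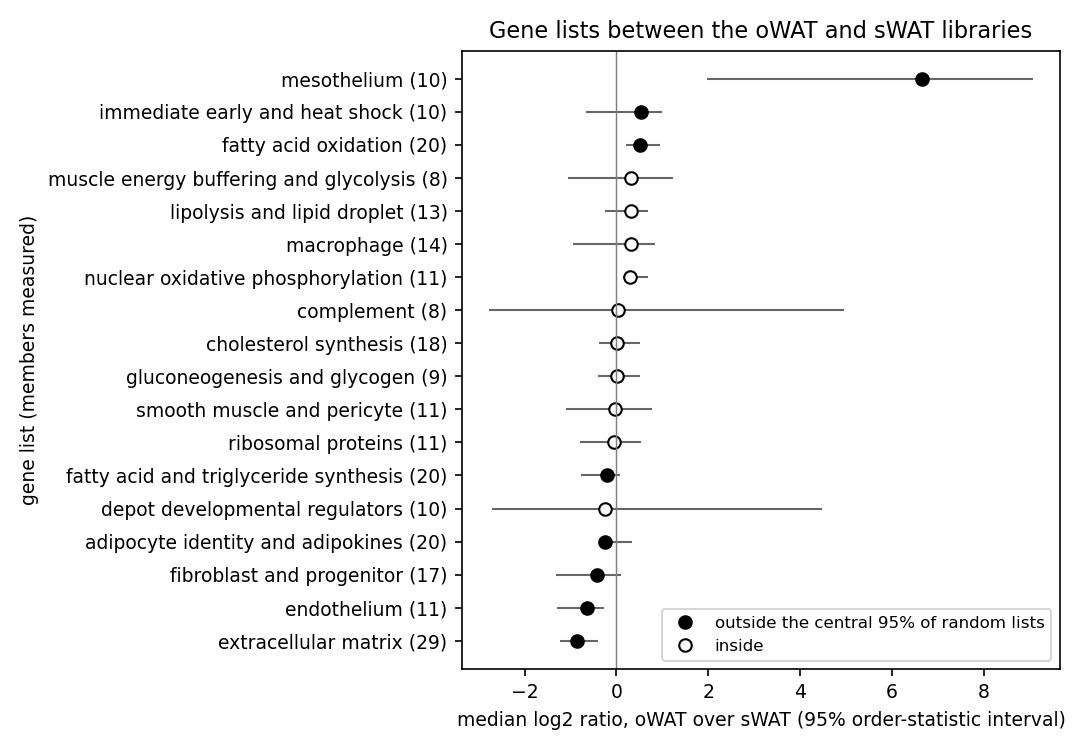
Median log2 ratio of oWAT over sWAT for each gene list with at least 8 measured members, with the number measured in parentheses; lines are 95% order-statistic intervals of the median, and filled circles lie outside the central 95% of random lists matched on expression. Mesothelium stands at 6.66 and extracellular matrix at -0.86.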

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

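No test is reported in this part; the shares were singled out after the values were seen. Each library holds counts that name no gene and enter no comparison. They made up 19.2% of the liver file (exact 95% binomial interval 19.1 to 19.3), 14.3% of the muscle file (14.2 to 14.4), 19.5% of the oWAT file (19.4 to 19.7) and 16.6% of the sWAT file (16.5 to 16.7). The sources used here do not say which reads these are, and no explanation was tested.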

How the results depend on the processing

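The comparisons of WAT against liver alone and of muscle against the WAT libraries alone (426 genes called) and the totals without the matrix list or with the counts that name no gene were chosen after the data were seen. No paired analysis was possible because each tissue has 1 pooled library and there are no replicates. Relative to library totals, TMM and DESeq2 scaling changed the log2 ratio of each gene by a median of 0.86 and 0.80 for liver, 0.41 and 0.36 for muscle, -0.56 and -0.55 for WAT, and -0.15 and -0.18 for oWAT over sWAT. The change differs between genes where the library compared differs, and the cause of changes in single results was not tested. Of the 533 genes called in liver all 533 kept the call with either scaling, and of the 390 in muscle 364 did; the counts rose to 772 (TMM) and 759 (DESeq2) in liver and to 441 and 430 in muscle. All 46 genes called in sWAT over oWAT kept it, as did 80 (TMM) and 74 (DESeq2) of the 94 in the other direction. Thinning to the smallest library left all 14 counts and correlations it was run on within 1.5 times or within their interval. The planned totals without mitochondrially encoded genes could not differ, as 0 such genes were among the names analysed here.

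The number of genes called became 838 (liver), 808 (muscle), 1165 (WAT), 1059 (oWAT over sWAT) and 539 (sWAT over oWAT) with a lower bound above 1, and 355, 232, 43, 33 and 3 with a bound above 4. TMM and DESeq2 scaling gave 68 and 71 for WAT and 70 and 82 for sWAT over oWAT. The wider interval of higher confidence gave 105 for WAT, 46 for oWAT over sWAT and 15 for sWAT over oWAT. A minimum of 30 counts gave 61 for oWAT over sWAT, and liver alone as comparator gave 1154 for WAT. The 50 most abundant genes took 39.8% in liver, 31.9% in muscle, 16.6% in oWAT and 23.9% in sWAT. Correlations without a minimum count were 0.59 (liver and muscle), 0.65 (liver and oWAT), 0.64 (liver and sWAT), 0.79 (muscle with oWAT and, at 0.79, with sWAT) and 0.91 (oWAT and sWAT). Pearson's r of log2 CPM was 0.25, 0.37, 0.36, 0.62 and 0.64 for all but the last pair.

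List medians outside the central 95% of random lists that changed sign were nuclear oxidative phosphorylation in liver (-0.41 with library totals, 0.032 with TMM, 0.030 with DESeq2) and muscle (-0.032, -0.030), and macrophage in WAT (-0.33, -0.32). Some medians inside that range changed sign as well, among them fatty acid synthesis and ribosomal proteins in WAT, at 0.35 and 0.28. Medians that moved beyond their interval with TMM and DESeq2 were macrophage in liver (-0.56, -0.58), nuclear oxidative phosphorylation (-1.83, -1.79), fatty acid synthesis (-0.47, -0.45), extracellular matrix (0.25, 0.27) and ribosomal proteins (-0.50, -0.49) in WAT, adipocyte identity in oWAT over sWAT (-0.41, -0.44) and, with DESeq2, nuclear oxidative phosphorylation there (0.12). A pseudocount of 2 gave, in liver, plasma proteins 6.49, coagulation 7.10, filament -6.28, fast fibre -7.31, slow fibre -4.06 and depot regulators -2.99. It gave, in muscle, plasma proteins -7.57, apolipoproteins -4.91, coagulation -7.62, xenobiotic metabolism -5.93 and filament 5.40, and in WAT plasma proteins -6.92, coagulation -7.88 and filament -5.64. Against the mean of the other libraries, liver had filament -6.19 and macrophage -0.70. Muscle then had plasma proteins -7.41, coagulation -7.35, fatty acid oxidation -0.77, thermogenic -0.66, extracellular matrix -0.96, immediate early 1.49, endothelium -0.91, fibroblast -0.95 and nerve 0.95. WAT had coagulation -7.89, nuclear oxidative phosphorylation -0.87, extracellular matrix 1.68, endothelium 1.30, fibroblast 1.51 and smooth muscle 0.67. With members of at least 1 count, depot regulators in liver stood at -3.08 and the urea cycle list in oWAT over sWAT at 1.31.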

Other observations

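The sets of genes lower in 1 tissue, the test of carry-over from liver, the test of transfer from oWAT to muscle, the test of adipocytes in muscle and the tests of fibroblast share with the bounds that decide them were chosen after the results were seen; the other tests below were written down before their results were seen.

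Of 4616 genes with at least 10 counts in each of the other 3 libraries, 545 were lower in liver than in each of them (282 with TMM and 287 with DESeq2 scaling). GSN had 15 counts in liver and was 292-fold higher in muscle (177 to 522), COL1A1 was 237-fold higher in muscle (135 to 459), and the matrix protease MMP2 had 2 counts in liver and was 404-fold higher in oWAT (111 to 3339). By lower bound FBLN2 (121-fold, 58.4 to 302), SCARA5 (1 count in liver, 293-fold, 52.3 to 11630), CCDC80 (103-fold, 47.2 to 283) and FHL1 (77.8-fold, 46.2 to 143) followed. CILP and FBN1, the fibrillin of elastic microfibrils, had 0 counts in liver and were at least 57.0-fold and 41.8-fold higher in the library closest to it. In muscle, 84 of 3813 genes were lower in muscle than in each of the others (50 with TMM, 53 with DESeq2 scaling). ANGPTL4, an inhibitor of lipoprotein lipase, PCK1 and MGST1 had 0 counts in muscle and were at least 13.1-fold, 11.5-fold and 8.50-fold higher elsewhere. AOX1 was 9.58-fold higher in oWAT (6.86 to 13.7), PYGL, the liver form of glycogen phosphorylase, 13.03-fold (6.35 to 31.1), TF 10.5-fold (6.24 to 18.8) and APOE 8.78-fold (4.92 to 17.1).

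The ribosomal protein list has 37 members, of which 25 had counts. These 25 made up 0.0375% of liver, 0.0355% of muscle, 0.0701% of oWAT and 0.0654% of sWAT counts. Transcript length was not used here, and whether the libraries hold short transcripts less fully than long ones was not tested. Abundance ranks and list counts therefore describe these libraries as sequenced. T and NK cell, B and plasma cell, red blood cell and epidermis lists had at most 2 measured members in each comparison and gave no median.

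Mesothelium genes stood at a median log2 ratio of 6.66 in oWAT over sWAT. The tables argue against carry-over from liver. The 9 called genes were higher in oWAT than in liver by a median log2 of 6.65 (3.08 to 7.60). Scaling by totals that a few genes dominate is argued against by size: DESeq2 factors changed the log2 ratio by a median of -0.18, against 6.66. With these factors 8 of the 9 kept the call, which adds little, since so small a change could remove only calls near the bound. A second list of mesothelial genes with no member in the first lay at the 100th percentile of random lists, with a median log2 of 3.18 (0.067 to 6.33) over 6 measured genes and 5 of them called: PKHD1L1, RSPO1, GPM6A, EZR and CRB2. A candidate explanation is therefore mesothelial cells in the oWAT tissue and not in the sWAT tissue; KRT19 is also in the cholangiocyte list, and WT1 and BNC1 are in that of depot regulators. A difference between the depots other than cell content stays open and untested, with 1 library each.

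Adipocyte genes appeared in the muscle library, with 43 counts of ADIPOQ. Transfer of oWAT reads is argued against: at the ADIPOQ share of 4.70% the 9 called mesothelium genes would have given 78.1 muscle counts, and they gave 0 (upper Poisson bound 3.69). Transfer of sWAT reads stays open. Of 219 genes with at least 200 counts in sWAT, 0.457% (CHIT1 alone, 5 counts in muscle against 484) lay below the ADIPOQ share of 3.85%. This share cannot decide the question, since genes that muscle expresses itself lie above it with or without transfer. GSN, for example, had 4399 counts in muscle and 4701 in sWAT. CHIT1 lay below what transfer would give, but is 1 gene. Adipocytes in the sampled muscle stay open as well: the other 14 called adipocyte genes had 693 muscle counts (642 to 747), above the 293 that the ADIPOQ share predicts, with LPL, CD36 and PLIN4 carrying 603 of them and CIDEC and CIDEA at 0. Expression of some of these genes by muscle itself would also give counts above that share, and was not tested.

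Extracellular matrix genes were higher in sWAT than in oWAT. Scaling by dominated totals is argued against by direction: DESeq2 factors changed the log2 ratio of oWAT over sWAT by a median of -0.18, towards sWAT. With that change the number of the 29 members called higher in sWAT could only stay or rise, and it went from 9 to 11. The tables argue against 3 collagens alone. The list without COL1A1, COL1A2 and COL3A1 had a median log2 of -0.82 (-1.19 to -0.27) at the 0th percentile of random lists. A larger share of fibroblasts in sWAT stays open for those 3 collagens: 13 fibroblast markers outside the matrix list had a median log2 of sWAT over oWAT of 0.42 (-0.51 to 1.32) but ran from -1.59 to 4.19 with a standard deviation of 1.41, which reaches the lowest collagen bound of 1.71. For the other 26 matrix genes, with a median of 0.82 (0.27 to 1.19), a fibroblast share cannot be told apart from a difference in expression, as the intervals overlap. A difference between the depots stays open and untested, with 1 library each.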
